A study of Mus musculus with 2 samples.

How the data were processed

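Droplet-based single-cell RNA sequencing with 3' chemistry (version 3.1) was described for 2 mouse samples, epiblast stem cells and day 2 embryoid bodies made from them, with 1 sample per group and a target of 10000 cells per sample per the labels. The deposited gene matrix holds raw UMI counts per feature and barcode, made with Cell Ranger 8.0.1 per the file headers. Seurat is named in the submitters' processing notes without a version, and no deposited values made with it were used here. The matrix holds 2578653 barcodes, 33696 genes and 12 tag oligos, and all barcodes share 1 suffix. The deposited tag table gives, per the file headers, a tag call and an assignment probability (a fraction between 0 and 1) for each of 21593 called cells. The labels describe separate channels for the samples, whereas the counts lie in 1 pooled matrix; the sources used here do not settle this difference. The genome build and annotation of the authors were not given in the sources used here, so genes are given by symbol and Ensembl identifier without coordinates.

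Only tags CMO311 and CMO312 appear in the tag table, and neither name matches a sample label. The matrix was therefore treated as 1 sample of pooled cells, as fixed before the data were examined for this case, and the planned comparison of embryoid bodies with epiblast stem cells was not made. No test between clusters or samples, standard error or p-value was computed. The intervals of the median share of UMIs and of rho in the closing section are bootstrap intervals over cells (1000 draws) and over genes (200 draws), and they describe this library only. That of the ribosomal difference is a bootstrap interval over 22 genes (1000 draws), which are not independent replicates. That of the difference between transcript mixtures comes from 1000 Poisson redraws of the counts. The planned condition that a cell carry 1 tag call was dropped for the pooled description, because it would have left 53 of the kept cells; the strict form was run as an alternative. No cell given to 1 tag had a probability of 0.99 or more; the range was 0.900 to 0.980, and unassigned cells had a median of 0.550.

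Kept cells had at least 1000 genes and at most 10% mitochondrial UMIs; 3345 called cells were under the gene minimum and 4308 over the mitochondrial maximum. Counts were scaled to 10000 per cell and log-transformed, and clusters were found with the Leiden method at resolution 0.5 on 2000 variable genes, 30 components and 15 neighbours, with S phase and G2/M phase genes left out of the variable genes. CPM were computed from UMIs summed over the cells of a cluster, with exact Poisson 95% intervals; folds used a pseudocount of 1 CPM. Shares of cells have exact binomial 95% intervals. A count of 0 was read as allowing up to 3 counts. For shares of cells with a UMI, cells were thinned to 2000 UMIs, which left out 294 shallower cells, 141 of them in cluster 8. Cell-free droplets were 72027 uncalled barcodes of 150 to 300 UMIs. Scrublet, at an expected doublet rate of 0.1, called 2145 kept cells doublets (12.7%), and these were left in except under 1 alternative. Free RNA was not removed in the reported values.

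The text names the 5 genes with the highest fold per cluster (at least 50 CPM) as its definition, and up to 4 members per list with the largest ratio between the highest and the lowest cluster of at least 100 cells (at least 20 CPM in the highest). Genes with provisional, mitochondrial or ribosomal names were left out of the first part. The rule, 18 lists of cell type markers and 24 other lists were fixed before the data were examined. Pou5f1, Sox2, Nanog, Dnmt3b and Prdm1, and the members named beside list counts, were chosen after their values were seen. The lists overlap: T, Mixl1, Krt8, Krt18, Dppa3 and Tfap2c, among others, each stand in more than 1. The genes Ero1l, Rnf12 and Cnbp2 were missing from the matrix. Some genes that the rule would name, and a list count that needs such a gene, are not reported here.

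The rule for naming clusters was set after the clusters had been seen, and only the markers were fixed before. A cluster took a name where at least 3 markers of the list were at least 2-fold higher with at least 20 CPM, where its 10 leading genes held at least 1 of them and more than 2 times as many as of the next list, and where it had at least 100 cells. The primitive streak list and the mesoderm, haematoendothelial and cardiac lists were read as 1. A fold of 1.5 had been used at first and was then put back to 2. Under 8 combinations of these conditions, clusters 1, 7 and 10 were named in 8 of 8. Cluster 6 was named in 4 of 8, since it lost its name where the lists were not read as 1. Clusters 3 and 4 were each named in 4 of 8, as primed epiblast at the lower fold and as primitive streak without the condition on the next list, and are left unnamed here. The gene whose share of cells is reported for each named cluster was changed to its list member with the highest fold after the first values had been seen.

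Tags and explanations of patterns were examined with the tests given in the closing section. Gene spans came from a mouse annotation that may differ from that of the authors; 99.2% of genes of at least 5 CPM were matched by identifier. Each ribosomal protein gene was compared with the 50 expressed genes nearest to it in span, and this replaced a correlation with gene span that only restated the pattern. The pluripotency and germline lists used there were chosen after the data were seen. On simulated counts with real means, 100 of 100 genes raised 4-fold, 0 of 100 raised 1.5-fold and 0 of 6463 unchanged genes passed the 2-fold criterion in each of 2 comparisons. The clustering returned 4 of 4 simulated groups, drawn from the profiles of clusters 1, 3, 6 and 7, with an adjusted Rand index of 0.976. Pairs such as clusters 9 and 1 were not simulated together, so this value does not bear on their separation. Both simulations held counting error only, with no other variation between cells. Alternatives covered the cell filter, doublets, clustering settings, scaling, pseudocount, free RNA and thinning. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scanpy 1.11.5, anndata 0.12.19, leidenalg 0.10.2, scikit-learn 1.9.0 and matplotlib 3.10.9.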

Results

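Single-cell RNA sequencing was described for 2 mouse samples, with 1 sample per group. They were epiblast stem cells, which are pluripotent cells of the primed state, and embryoid bodies, which are aggregates of differentiating cells, taken on day 2 after being made from the stem cells. The deposited counts form 1 pooled matrix, and the names of its cell tags match no sample label. No value below therefore belongs to either sample, and epiblast stem cells could not be compared with embryoid bodies. Whether the matrix holds 1 or both of the samples was not given in the sources used here. The pooled library is described as 1 sample, by cluster of cells, with no test between clusters. Intervals of levels and of shares of cells are 95% intervals and cover counting error only. Of 21593 called cells, 16841 (78.0%) were kept, with a median of 6473 UMIs and 2682 genes per cell and a range of 1265 to 34748 UMIs. Kept cells held 121114764 UMIs in all, from 26873 genes with at least 1 UMI.

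The kept cells fell into 12 clusters, of which 4 met every condition of the naming rule. Clusters 4, 9 and 12 also had at least 3 raised markers of their leading list but failed another condition. Naive pluripotency-like cells (cluster 1) made up 28.9% of kept cells (exact binomial interval 28.2 to 29.6%, 4863 cells). Primitive streak and mesoderm-like cells (cluster 6) made up 4.20% (3.90 to 4.51%, 707 cells). Fibroblast or feeder-like cells (cluster 7) made up 3.57% (3.29 to 3.86%, 601 cells), and two-cell-like cells (cluster 10) 1.25% (1.08 to 1.43%, 210 cells). Clusters 2, 3, 4 and 5 held 21.7%, 18.5%, 10.3% and 5.52% of kept cells, and clusters 8, 9, 11 and 12 held 3.42%, 2.01%, 0.481% and 0.160%. These 8 clusters were left unnamed and are described by their genes. Gene levels are CPM from summed UMIs, and folds are against all other kept cells. A gene concentrated in cluster 7 can therefore count as lower elsewhere. List counts are out of all members in the matrix. A member counts as higher only with at least 20 CPM in the cluster, and as lower only with at least 20 CPM in the other cells. A cluster's leading genes define it and are not a separate result. The same holds for counts of higher members of the lists that name a cluster, since the naming rule uses them. It also holds for shares of cells with Zfp42, Mixl1, Col3a1 or Zscan4d in their own clusters, as these are leading genes.

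**Figure D1:**
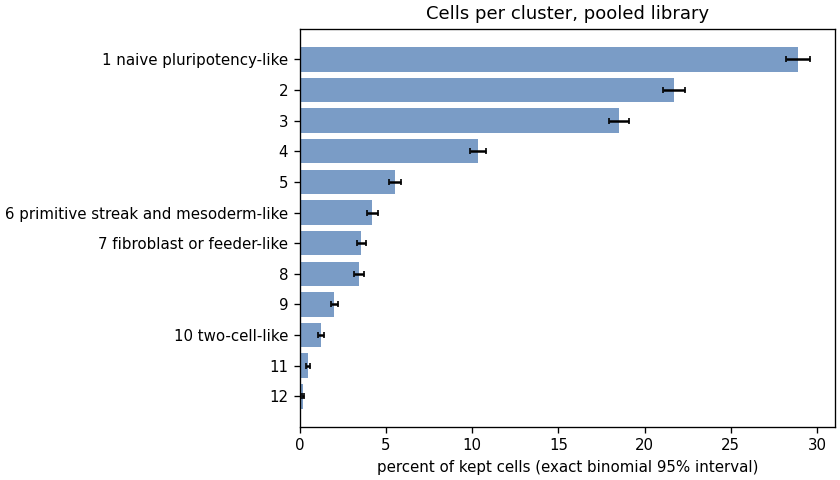
Percent of kept cells in each of the 12 clusters of the pooled library, with exact binomial 95% intervals as error bars. Cluster 1 held 28.9% of the cells and cluster 12 held 0.160%.

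In the naive pluripotency-like cluster, 13 of 16 naive pluripotency genes were at least 2-fold higher than in the other cells, and 1, Spp1, was at least 2-fold lower. Spp1 stood at 5392 CPM in cluster 7, which lies in the reference, and at 25.3 CPM in cluster 3. Its lower call therefore depends on the reference. Zfp42 (ENSMUSG00000051176), a marker of naive embryonic stem cells, stood at 1035 CPM against 154 in the other cells. Esrrb (ENSMUSG00000021255), a nuclear receptor of the naive network, stood at 98.8 against 15.3 CPM, and Klf2 (ENSMUSG00000055148) at 824 against 189 CPM. With each cell thinned to 2000 UMIs, 78.4% of these cells had a UMI of Zfp42 (77.2 to 79.5%), against 11.3% of the fibroblast or feeder-like cells (8.86 to 14.1%), which should lack it. The median depths before thinning were 6981.5 and 6999 UMIs. Nanog and Sox2, shared by both pluripotent states, were also at least 2-fold higher in cluster 1, while Fgf5 and Pou3f1, markers of the primed epiblast, were at least 2-fold lower. The primed epiblast list as a whole was not lower: with these 4 and Cldn6, 2 of its 18 members were higher and 3 lower, and its median log2 ratio was 0.11. Of the DNA methylation and pluripotency chromatin genes, 3 of 14 were at least 2-fold higher, namely Dnmt3l, Tet1 and Tet2, and none was as much lower.

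Clusters 2 and 3 each had 11 of 16 naive pluripotency genes at least 2-fold lower and none as much higher. Pou5f1, a core pluripotency factor, stood at 532 CPM (524 to 541) in cluster 2 and 649 CPM (638 to 661) in cluster 3, against 204 CPM in the fibroblast or feeder-like cells. Dnmt3b, a de novo methyltransferase of the primed epiblast, stood at 381 CPM (374 to 388) and 450 CPM (441 to 460), and at 195 CPM (191 to 200) in cluster 1. Fgf5 stood at 41.8 and 49.9 CPM, against 9.79 CPM in cluster 1. None of the 18 primed epiblast genes reached a 2-fold excess in either cluster, and Nanog was at least 2-fold lower in both. Clusters 2 and 3 lie in each other's reference, and cluster 1 lies in both, so these folds and those of the naive genes depend on that reference. Cluster 2 was led by Hs3st4, Ptprt, Anks1b, Hdac9 and Ano3, and cluster 3 by Car4, Mt1, Pim2, Pou3f1 and Phlda2. Across 10796 genes, which are not independent replicates, the log2 ratio to the other cells went with gene span in opposite ways (Spearman's rho 0.37 in cluster 2 and -0.52 in cluster 3).

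Cluster 4 carried streak, neural and retinoic acid genes in the sum over its cells. Whether single cells carried them together was not examined, and 16.9% of the cluster's cells were called doublets. Of the primitive streak genes 4 of 15 were at least 2-fold higher (T, Fgf8, Wnt8a and Nkx1-2), as were 3 of 14 neuroectoderm genes (Sox1, Sox3 and Fabp7). Crabp2, Hoxb1, Meis1 and Meis2 of the retinoic acid response list were also at least 2-fold higher. Meis2 (ENSMUSG00000027210), a homeodomain factor, stood at 375 CPM against 21.1 in the other cells, and Fgf8 (ENSMUSG00000025219), a growth factor of the streak and tail bud, at 406 against 28.7 CPM. A UMI of Meis2 was found in 45.0% of cluster 4 cells after thinning (42.6 to 47.4%), against 1.43% in cluster 1. Of the naive pluripotency genes 14 of 16 were at least 2-fold lower and 1, Gbx2, was at least 2-fold higher. Pou5f1 stood at 546 CPM (534 to 559).

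In the primitive streak and mesoderm-like cluster, 8 of 15 primitive streak genes, 5 of 14 nascent and paraxial mesoderm genes, 8 of 13 lateral plate and extraembryonic mesoderm genes and 5 of 12 haematoendothelial genes were at least 2-fold higher; 1 of the nascent and paraxial genes, Tcf15, was at least 2-fold lower. Most other members were under 20 CPM on both sides. Summed over all members, the primitive streak list stood at 1006 against 139 CPM and the haematoendothelial list at 336 against 34.7 CPM. T, or brachyury, stood at 134 CPM (123 to 144), Mesp1, a factor of nascent mesoderm, at 106 CPM (97.1 to 116), Hand1 at 79.9 CPM (72.1 to 88.4) and Kdr, a VEGF receptor, at 73.8 CPM (66.3 to 82.0). Mixl1 had 432 UMIs (90.9 CPM) here and 0 UMIs in cluster 9, which allows up to 1.39 CPM there. After thinning, 13.3% of these cells had a UMI of Mixl1 (10.9 to 16.1%), against 0 of 593 fibroblast or feeder-like cells, which allows up to 0.506%; the median depths were 5823 and 6999 UMIs. BMP target genes were at least 2-fold higher in 8 of 14 cases, with Msx2 at 85.0 CPM and Bambi at 125 CPM, and WNT target genes in 5 of 16. Of the EMT and mesenchymal genes 8 of 14 were at least 2-fold higher and 1, S100a4, was as much lower. S100a4 stood at 518 CPM in cluster 7, which lies in the reference, and at 0.431 CPM in cluster 1. Its lower call therefore depends on the reference. Of the epithelial adhesion genes 8 of 15 were at least 2-fold lower, while 4, Krt8, Krt18, Krt19 and Dsp, were at least 2-fold higher. Of the primed epiblast genes 9 of 18 were at least 2-fold lower. Pou5f1 stood at 197 CPM (184 to 210), beside 204 CPM (192 to 217) in the fibroblast or feeder-like cells. These levels are sums over the cluster, and 19.1% of its cells were called doublets.

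**Figure D2:**
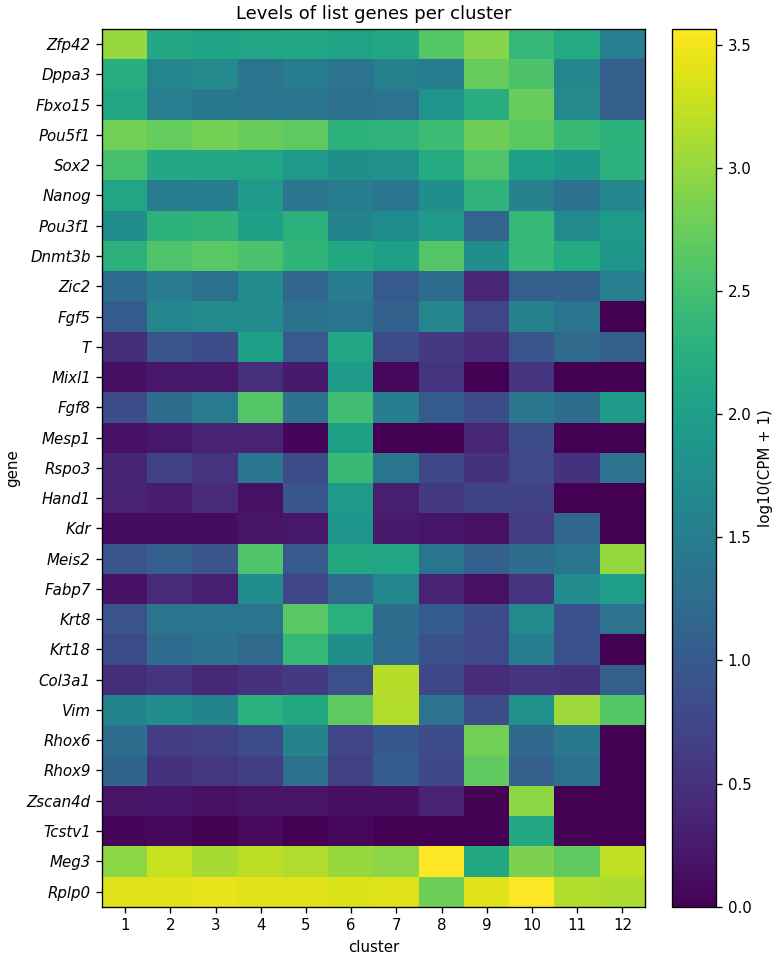
Levels of list genes in each cluster, coloured by log10 of CPM plus 1. Zfp42 reached 1035 CPM in cluster 1, Col3a1 1528 CPM in cluster 7 and Zscan4d 893 CPM in cluster 10.

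Cluster 5 carried epithelial genes. Of the epithelial adhesion genes 11 of 15 were at least 2-fold higher, including Cdh1, Cldn4 and Cldn7. Krt8 (ENSMUSG00000049382) and Krt18 (ENSMUSG00000023043), the keratins of simple epithelia, stood at 442 against 24.2 CPM and at 239 against 15.1 CPM. A UMI of Krt8 was found in 44.0% of these cells after thinning (40.8 to 47.3%), against 1.52% of the fibroblast or feeder-like cells. Pou5f1 stood at 476 CPM (460 to 492), and 9 of 16 naive pluripotency genes were at least 2-fold lower. Of the dissociation and immediate early genes 5 of 17 were at least 2-fold higher.

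In the fibroblast or feeder-like cluster, 13 of 13 fibroblast genes and 12 of 14 EMT and mesenchymal genes were at least 2-fold higher. Col3a1 (ENSMUSG00000026043), a fibrillar collagen, stood at 1528 against 2.34 CPM, Dcn (ENSMUSG00000019929), a matrix proteoglycan, at 643 against 0.680 CPM, and Mmp3 (ENSMUSG00000043613), a matrix protease, at 1465 against 1.39 CPM. A UMI of Col3a1 was found in 74.2% of these cells (70.5 to 77.7%), against 0.353% of cluster 1. Cell cycle genes were low, with 21 of 30 S phase genes and 28 of 30 G2/M phase genes at least 2-fold lower. Of the dissociation and immediate early genes 6 of 17 were at least 2-fold higher, namely Fos, Jun, Junb, Egr1, Ier3 and Zfp36. Cdkn1a, an inhibitor of the cell cycle, stood at 866 CPM (840 to 892), against 39.3 CPM in cluster 9. Of the primed epiblast genes 17 of 18 were at least 2-fold lower. The 25 Hox genes together stood at 253 against 32.3 CPM. Pou5f1 still reached 204 CPM (192 to 217), and 23.1% of the cluster's cells were called doublets.

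Cluster 8 held shallow cells, with a median of 2644 UMIs and 8.16% mitochondrial UMIs, against 6473 UMIs and 3.14% over all kept cells. These values depend on the cell filter: the cluster's share went from 3.42% to 16.6% with a lenient filter (at least 500 genes and at most 20% mitochondrial UMIs), and the cluster was not recovered with a strict one (at least 2000 genes and at most 5%). Of the mitochondrially encoded genes 12 of 13 were at least 2-fold higher, while 20 of 22 cytosolic ribosomal protein genes and 14 of 20 nuclear OXPHOS genes were at least 2-fold lower. Rplp0, a ribosomal stalk protein, stood at 607 CPM (569 to 646), against 3599 CPM (3506 to 3694) in cluster 10. The noncoding RNAs Meg3, at 3664 CPM (3572 to 3758), and Xist, at 680 CPM (641 to 722), were at their highest here among clusters of at least 100 cells. Without mitochondrial and ribosomal protein genes in the total, all genes of cluster 8 shifted by -0.17 on the log2 scale, and the ribosomal median went from -1.79 to -1.96.

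Cluster 9 was led by Rhox9 (ENSMUSG00000068048), at 495 against 7.50 CPM, and Rhox6 (ENSMUSG00000006200), at 641 against 10.9 CPM, which are X-linked homeobox genes of the placenta and germ line. Of the primordial germ cell genes 7 of 10 were at least 2-fold higher, among them Prdm1 at 66.1 CPM (55.7 to 77.9), Tfap2c at 212 CPM (193 to 232) and Dppa3 at 539 CPM (509 to 571). Naive pluripotency genes were at least 2-fold higher in 9 of 16 cases (and lower in 1, Spp1) and primed epiblast genes at least 2-fold lower in 9 of 18, while Sox2 and Nanog were at least 2-fold higher. For Spp1 the other cells include cluster 7, at 5392 CPM, so that call depends on the reference. Dnmt3b stood at 59.2 CPM (49.4 to 70.4), and the imprinted noncoding RNA Meg3 at 148 CPM (132 to 165), each the lowest among clusters of at least 100 cells. A UMI of Dppa3 was found in 61.4% of these cells (56.0 to 66.6%), against 3.88% of the fibroblast or feeder-like cells. Dppa3 also stands in the naive pluripotency list. Tfap2c was raised in cluster 1 as well, at 78.9 against 18.1 CPM in the other cells, so it is not particular to cluster 9. Of 8 other clusterings, 1 recovered cluster 9, and in each of the others its best match was the cluster that best matched cluster 1. Rhox genes are a family of similar sequence, so UMIs can be shared between its members.

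In the two-cell-like cluster, 8 of 8 genes of the two-cell-like list were at least 2-fold higher. Zscan4d (ENSMUSG00000090714), of a family active in 2-cell embryos, had 893 CPM (847 to 941) here and 0 UMIs in cluster 9, which allows up to 1.39 CPM there. Tcstv1 stood at 142 CPM (124 to 162), and Eif1ad10 led the cluster at 1527 against 1.27 CPM in the other cells. A UMI of Zscan4d was found in 44.4% of these cells (37.6 to 51.5%), against 0.145% of cluster 1. Pou5f1 stood at 461 CPM (428 to 496). The Zscan4 and Eif1ad genes are families of similar copies, so the split of UMIs within each family is uncertain.

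The remaining clusters held 81 and 27 cells. Cluster 11 was led by Lyz2 (ENSMUSG00000069516), Ccl6, C1qa, C1qc and Wfdc17, genes of macrophages, with a UMI of Lyz2 in 78 of 80 thinned cells against 17 of 4818 in cluster 1. Cluster 12 was led by Nrxn3 (ENSMUSG00000066392), Dcx, Dcc, Nhlh2 and Sst, genes of neurons. In cluster 12, which held 91778 UMIs in all, the 25 Hox genes together had 90 UMIs, or 981 against 40.6 CPM in the other cells, and the 14 neuroectoderm genes had 99 UMIs, or 1079 against 97.8 CPM.

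Counts of the cell tags differed between clusters, and they are given here as values with no assignment of cells to samples. The median count of tag CMO311 was 1054 UMIs over all kept cells and 830 over cell-free droplets, and that of CMO312 was 400 and 340 UMIs. In the primitive streak and mesoderm-like cluster the medians were 869 UMIs of CMO311 and 2559 of CMO312, and in cluster 4 they were 2385 and 327. The authors' table gave 59 called cells to CMO311 and 64 to CMO312, and left 21465 of 21593 (99.4%) unassigned.

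**Figure D3:**
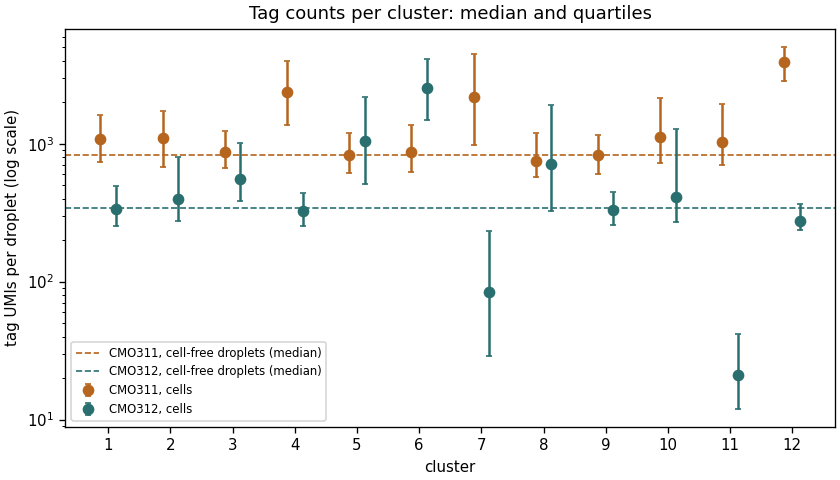
Median UMIs of both tags per droplet in each cluster, on a log scale, with bars from the lower to the upper quartile and dashed lines at the medians of cell-free droplets. CMO312 had a median of 84 UMIs in cluster 7 and 21 in cluster 11, under its cell-free median of 340.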

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

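The tests of free RNA (both), of own expression, of lost cytoplasmic RNA and of trophoblast cells were chosen only after their results had been seen. The bounds of the tests of mixed droplets, of depth and of DNA methylation were set before. The pluripotency and germline lists that the tests of mixed droplets and of DNA methylation used were chosen after the data were seen. No biological explanation from the design was tested, since cells could not be assigned to the groups.

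Tag counts, which the comparisons of gene levels do not use, stood above the 90th percentile of cell-free droplets (1228 UMIs of CMO311 and 478 of CMO312) in 7 medians. For CMO311 these were 2385 UMIs in cluster 4, 2168 in cluster 7 and 3937 in cluster 12. For CMO312 they were 555.5 UMIs in cluster 3, 1049 in cluster 5, 2559 in cluster 6 and 714 in cluster 8.

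Pluripotency transcripts appeared in the fibroblast or feeder-like cluster and in the macrophage-gene cluster 11. A set of 10 such transcripts, including Pou5f1, Sox2 and Zfp42, had a mean of 13.7 UMIs per cell in cluster 7, 9.14 times that of a cell-free droplet (8.94 to 9.34), or 4.07 times without called doublets (3.92 to 4.22), and 7.18 times in cluster 11, or 3.35 times without them; this argues against free RNA as the source of the whole amount. The median cluster 7 cell had 2 UMIs, 1.33 times the cell-free mean, so free RNA stays a candidate source in the typical cell. This sets a median, which is a whole count, against a mean. Both comparisons assume as much free RNA in these droplets as in cell-free droplets, which was not examined. Median CMO312 was 84 UMIs in cluster 7 and 21 in cluster 11, under the cell-free median of 340. Own expression stays open: the mixtures of the transcripts differed between the clusters by a median log2 difference of only 0.10 (0.09 to 0.36), but called doublets held 65.8% of these UMIs in cluster 7 and 63.2% in cluster 11, so this comparison decides nothing. Amounts were uneven, with none of the transcripts in 17.0% of cluster 7 cells and a median share of UMIs per cell of 0.376 of the mean (0.318 to 0.417), so droplets that also held a pluripotent cell are a candidate explanation for the excess over free RNA, as is expression in part of the cells.

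Cluster 8 was shallow, mitochondrial and led by long genes such as Foxp2. Low depth alone was argued against: after all cells were thinned to 1000 UMIs, 97.4% of its cells (95.7 to 98.5%) again shared 1 cluster, although only 73.7% of the 761 cells in that cluster came from cluster 8. The lean to long genes held across 10796 genes (rho 0.72, interval 0.71 to 0.73), which describes the pattern and tests no cause. Cytosolic ribosomal protein mRNAs, 22 genes that are not independent replicates, were already known to be lower there. They lay below genes of the same span by a median log2 difference of -0.73 (bootstrap interval over genes -0.95 to -0.55). Cells that lost cytoplasmic RNA may account for this; a cell state with fewer ribosomal mRNAs stays open.

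Cluster 9 carried Rhox6 and Rhox9, known from the placenta, with Dppa3 and Tfap2c. The rest of the trophoblast list, 10 genes that include Gata2, stood at 46.2 against 18.2 CPM. The ratio of 2.54 (2.06 to 3.09) met the bound of 2 first set for trophoblast cells. Gata2 alone, with 45 UMIs, gave 20.8 of the 46.2 CPM, so the ratio rests in large part on that gene. A condition on keratins was added only after that bound had been met. Krt8 and Krt18, abundant in trophoblast, stood at 0.133 of their level in the other cells (0.0843 to 0.1996). The other cells include cluster 5, with Krt8 at 442 CPM and Krt18 at 239 CPM, which lowers this ratio. Cluster 9 was still the lowest among clusters of at least 100 cells, at 5.55 CPM of Krt8 and 5.09 CPM of Krt18. The keratins argue against trophoblast cells, although the list alone met its bound. Loss of DNA methylation could also raise Rhox genes, and the median of germline genes that depend on it lay at percentile 95.86 of random lists, between the bounds set for and against, so it stays open.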

How the results depend on the processing

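The restriction to cells given to 1 tag, the subtraction of the cell-free profile and the removal of cluster 8 from the other cells were chosen after seeing the data. Only 53 kept cells were given to 1 tag, so the shares in tagged cells rest on few cells, and a share of 1.89% is 1 cell. Every count of list members examined, 44 values for naming lists and 52 for other lists, stayed within 1.5 times the reported count under each alternative run. For cluster 6 the naming list examined was the primitive streak list alone. Only the filter and doublet alternatives changed the cells of a cluster, and other clustering settings were not run for these counts. For cluster 9 the filter and doublet alternatives were not run, since it was not recovered under them. The share of the naive pluripotency-like cluster was 23.8% with the lenient cell filter, 26.2% with the strict one, 26.7% with 4000 variable genes, 30.1% with cell cycle genes kept, 32.3% at resolution 0.25 and 17.0% in cells given to 1 tag; at resolution 1.0 it was not recovered. The primitive streak and mesoderm-like share was 3.62% with the strict filter, 3.47% without doublets, 3.66% with 50 components and 3.77% in tagged cells, and the cluster was not recovered at resolution 0.25. The fibroblast or feeder-like share was 2.85% with the lenient filter, 3.22% with the strict one, 3.09% without doublets, 3.15% at resolution 1.0 and 20.8% in tagged cells. The two-cell-like share was 0.842% with the strict filter and 1.89% in tagged cells. With cells thinned to 1000 UMIs, thinned to 5000 or not thinned, a UMI was found for Zfp42 in 59.4%, 93.1% and 94.7% of cluster 1, for Mixl1 in 8.20%, 26.9% and 27.4% of cluster 6, and for Col3a1 in 57.9%, 84.8% and 84.9% of cluster 7; for Zscan4d in cluster 10 it was 55.1% at 5000 UMIs and 61.4% not thinned. The thinning depth itself sets these shares; the cause of the other shifts was not tested. Among unnamed clusters 31 shares left their interval, those in the few tagged cells among them, and 23 stayed. Cluster 8 went from 3.42% to 16.6% with the lenient filter and was not recovered with the strict one or 50 components; cluster 2 went from 21.7% to 13.1% without doublets and 12.6% at resolution 1.0 and was not recovered with the strict filter, 4000 variable genes or resolution 0.25, and cluster 11 from 0.481% to 0.209% with the strict filter. Cluster 12 was not recovered with either filter, resolution 1.0 or 50 components, clusters 3 and 5 not at resolution 0.25, and cluster 9 only at resolution 1.0. In tagged cells clusters 3, 5 and 11 held 7.55%, 17.0% and 1.89%, and clusters 8, 9 and 12 none. The planned comparison of the groups and its alternatives were not run, since no tag matched a label, and the tag probability of 0.99 left no cell. No paired analysis was possible because the pooled cells could not be assigned to samples.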

Other observations

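No test was run for the values in this part, and the germline list was chosen after the data were seen. Imprinted genes differed between clusters. H19, a maternally expressed noncoding RNA, stood at 398 CPM (380 to 416) in the fibroblast or feeder-like cluster and at 3.72 CPM (3.05 to 4.50) in cluster 2. Dlk1, a paternally expressed NOTCH ligand homologue, stood at 77.6 CPM (70.0 to 85.7) in cluster 7 and 0.925 CPM (0.112 to 3.34) in cluster 9. In cluster 9, 6 of 20 imprinted genes were at least 2-fold lower and 1, H19, was at least 2-fold higher. Rian, a noncoding RNA of the same locus as Meg3, stood at 66.1 CPM (55.7 to 77.9) there.

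Slc2a3, a glucose transporter, stood at 748 CPM (712 to 785) in cluster 9 and at 97.2 CPM (88.7 to 106) in the fibroblast or feeder-like cluster. The glycolysis list as a whole did not follow it: in cluster 9, 2 of 17 members were at least 2-fold higher and 2 at least 2-fold lower. Germline genes that depend on DNA methylation were at least 2-fold higher in 5 of 24 cases in the two-cell-like cluster, with Smc1b at 77.2 CPM (64.0 to 92.2) and Stk31 at 68.2 CPM (55.9 to 82.4).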
